A study of Mus musculus with 31 samples.

How the data were processed

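Messenger RNA of sorted mouse Th17 cells was measured by paired-end sequencing of polyadenylated RNA from about 2000 cells per library, per the labels, with a modified SMART-Seq2 protocol and Nextera XT tagging. The protocol keeps no strand information, so reads of a gene and of an antisense transcript cannot be separated. The values are counts per gene as deposited, without normalisation, in 3 tables of 31053 gene symbols each, 1 table per experiment. The submitters' processing notes name RSEM 1.3.3 and the mouse build mm10. Every column was matched to a library by its label, and 0 columns were left without a library. Gene positions were taken from GENCODE M21 on GRCm38 (mm10), which held 30464 of the symbols. The other 589 symbols carried no position but were tested like the rest.

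The 31 libraries were grouped by their labels. The Cyp11a1 experiment had 4 WT and 6 cKO libraries, the GR experiment 5 WT and 4 cKO libraries, and the in vitro experiment 3 libraries in each of 4 groups. Each experiment was fitted alone, since experiment and sequencing run cannot be separated between tables. The labels do not state whether libraries came from separate recipients or cultures, so p-values of genes and marker sums measure the spread among libraries. The camera p-values of gene lists, described below, compare a list with the other tested genes. At a preset correlation they do not use how the members of a list vary together among libraries. The p-values of gene positions come from random draws of genes. Chi-square statistics of replicate pairs per degree of freedom lay between 2.79 and 142 over genes with at least 20 counts, so the replicates spread more than counting error.

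Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM, and groups were compared by robust quasi-likelihood F tests with a Benjamini-Hochberg adjusted p threshold of 0.05. The in vitro groups shared 1 fit, from which 5 pairwise comparisons and the interaction of dexamethasone and TGF-β1 were taken. Levels are CPM, edgeR's counts scaled by library size and TMM factor, given as mean ± SD over the libraries of a group. Effects are log2 fold changes ± standard error (SE). The smallest level a library could show was taken as 3 counts of its total, and these floors, like all intervals, cover counting error only.

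The gene lists, the comparisons and the rule for named genes were fixed before the data were examined. There were 25 lists with 407 genes in all, of which 3 symbols were matched through synonyms. They covered Th17 identity, homeostatic Th17, inflammatory Th17, Th1, Th2, Treg, co-inhibitory receptors, stem-like and memory T cells, glucocorticoid-induced genes, NF-kB targets, TGF-β and Smad targets, steroid synthesis, cholesterol synthesis, glycolysis and hypoxia, proliferation, type I interferon response, apoptosis, migration receptors and immediate-early stress genes. The remaining 6 lists held markers of T cells, myeloid cells and microglia, neutrophils, B and plasma cells, NK and CD8 T cells, and neural and glial cells. A list with at least 5 tested members was tested two-sided with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 21 lists tested in a comparison. Each list was also tested with an estimated correlation and with fry. The number of its members past the threshold was counted over all genes and adjusted over the list alone. Marker lists were also summed as CPM per library for 8 lists and compared by exact two-sided permutation tests on log2 sums.

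Named genes were Cyp11a1 and Nr3c1 in every comparison, and up to 10 genes per direction with the largest log2 fold change among those past the threshold with a mean log2 CPM of at least 4. Predicted genes, RIKEN clones, receptor variable segments and pseudogenes were left out of the naming. Where no gene passed, 5 genes per direction with the smallest p were named. Other genes are named as list members, or were singled out after their values were seen where the text says so. The values of some list members are not reported here.

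The alternatives were other scaling methods, no low-count filter and a mean count filter of 50, DESeq2 1.42.0, limma voom with sample weights, a term for replicate number, the compared groups alone, and each library left out in turn. A group of 8 predicted genes, including Gm10800, Gm10801 and Gm26870, each held at least 0.2% of the counts of a library and varied together with a correlation of at least 0.95. Fits without these genes, fits with their share or the myeloid marker sum as a covariate, fits without pairs of libraries that stood apart, and marker sums of the sorted cells without each library, were added after seeing the data. Every comparison of groups was repeated on other splits of its libraries, all 10 for 3 against 3 and 100 drawn splits elsewhere. The tests were checked on simulated counts in which 200 genes were changed. At a 2-fold change 181, 131 and 158 of these were recovered in the layouts of the Cyp11a1, GR and dexamethasone comparisons, with 11, 12 and 8 false calls. At a 1.5-fold change 98, 0 and 63 were recovered. The changed genes were drawn from those with a mean log2 CPM above 3, and the simulated libraries varied independently. These numbers therefore do not cover genes at lower levels or differences in composition shared by many genes, as between the GR libraries. The correlation and covariance of dexamethasone and TGF-β1 effects were set against 50 simulated experiments with unchanged groups and shared controls.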

Results

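The data describe mouse T helper 17 (Th17) cells, CD4 T cells that make interleukin 17, in 3 RNA sequencing experiments. For the Cyp11a1 and GR experiments, naive T cells carrying the transgenic 2D2 receptor for a myelin protein were isolated from wild-type (WT) or conditional knockout (cKO) mice and turned into homeostatic Th17 cells in culture. After transfer into mice lacking Rag1, which have no T or B cells of their own, they caused experimental autoimmune encephalomyelitis. The transferred cells were sorted from the central nervous system when disease peaked. GR, the glucocorticoid receptor, is the product of Nr3c1. In the in vitro experiment, inflammatory Th17 cells were cultured for 2 days without addition, with the synthetic glucocorticoid dexamethasone (Dex), with the cytokine TGF-β1, or with both. The libraries held 4322688 to 5118543 counts in the Cyp11a1 experiment, 3552871 to 5623305 in the GR experiment and 2769203 to 4291149 in vitro. Between 14814 and 16408, 15233 and 16936, and 13878 and 15027 genes had a count. A count of 0 allowed a level of up to 0.522 to 0.795, 0.495 to 1.05 and 0.632 to 1.13 CPM in the libraries of these experiments. A group of 8 predicted genes resembling repeats took 12.7% to 36.4%, 13.9% to 52.9% and 8.85% to 27.9% of the counts.

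The Cyp11a1 comparison asked what changes in homeostatic Th17 cells of the inflamed nervous system when Cyp11a1 is targeted, the gene of the mitochondrial enzyme that turns cholesterol into pregnenolone. Cyp11a1 itself (chromosome 9, 58006411 to 58027023) had 0 counts in all 4 WT libraries and in 5 cKO libraries, and 4 counts in cKO replicate 2, so its loss was not detectable. The in vitro libraries held 64 to 217 counts of Cyp11a1 at lower total counts, so depth alone does not give the 0 counts in WT. The largest named increase was in H2-Eb1, an MHC class II chain that presents antigen (chromosome 17, 34305867 to 34316674), at 56.1 ± 20.4 CPM in cKO (n = 6) against 12.8 ± 5.01 CPM in WT (n = 4). Complement genes rose as well, C1qb (chromosome 4, 136880129 to 136886187) from 64.6 ± 3.87 to 123 ± 27.7 CPM and C1qa (chromosome 4, 136895917 to 136898803) from 45.5 ± 3.99 to 84.3 ± 17.7 CPM. The lysosomal protease gene Ctsd (chromosome 7, 142375911 to 142388038) rose from 445 ± 13.7 to 646 ± 22.2 CPM. Tnfrsf25, which encodes the T cell costimulatory receptor DR3 (chromosome 4, 152115934 to 152120119), fell from 55.9 ± 7.45 to 34.0 ± 5.71 CPM.

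In edgeR, 18 of 10125 genes passed the threshold between Cyp11a1 cKO and WT, 14 higher and 4 lower in cKO, and 11 changed at least 2-fold. In each of the 18 genes, all 6 cKO libraries lay on 1 side of all 4 WT libraries, which chance gives with a probability of 0.00952 per gene, though these genes were picked for differing between the same groups. The log2 fold change was 2.14 ± 0.31 for H2-Eb1 (edgeR adjusted p = 0.0192) and 0.54 ± 0.06 for Ctsd (edgeR adjusted p = 0.000764). Fcer1g, the signalling chain of Fc receptors (chromosome 1, 171229572 to 171234365), rose by 1.02 ± 0.18, C1qb by 0.92 ± 0.15 and C1qa by 0.89 ± 0.15, with edgeR adjusted p = 0.0366, 0.0266 and 0.0266. Wdfy1 (chromosome 1, 79702262 to 79776143) rose by 1.02 ± 0.18 and the interferon-inducible Ifitm2 (chromosome 7, 140954837 to 140955987) by 0.63 ± 0.11, with edgeR adjusted p = 0.0434 and 0.0321. Tmem254c (chromosome 14, 26063919 to 26067355) fell by 0.93 on the log2 scale and Tnfrsf25 by 0.72, with edgeR adjusted p = 0.0192 and 0.0456. Nr3c1 stood at 10.2 ± 1.32 against 10.3 ± 2.07 CPM (edgeR adjusted p = 0.995). Without WT replicate 1 the count was 11 genes, without WT replicate 4 it was 10, and without cKO replicate 5 it was 9. DESeq2 called 60 genes and limma voom 6, 3 genes passed with the myeloid marker sum as a covariate, and 6 without WT replicates 1 and 4, the last 2 fits being chosen after seeing the data. The myeloid marker sum did not overlap between the groups, 1026 to 2005 CPM in cKO against 885 to 928 CPM in WT. The fit with it therefore cannot separate genotype from myeloid RNA, and the fall to 3 genes does not tell which of them the calls follow.

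The other 9 genes past the threshold lay outside the naming rule and were singled out after their values were seen. Eps8l1 had 189 counts over the cKO libraries and 3 over the WT libraries, and Syce1, a meiotic gene, had 265 and 4. Rpl39l stood at 14.1 CPM against 0.951, Napsa, an aspartic protease gene, at 10.3 against 3.69, Xlr3b at 14.9 against 5.52 and Mef2c, a transcription factor gene, at 3.51 against 0.855 CPM in cKO and WT. The predicted gene Gm42047 stood at 71.9 against 28.4 CPM. Rab4a, which encodes an endosomal GTPase, was lower in cKO at 2.94 ± 1.16 against 13.6 ± 3.89 CPM, as was the clone A530040E14Rik at 10.9 against 20.5 CPM.

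Markers of myeloid cells and microglia rose together in the Cyp11a1 cKO libraries: 19 of 20 tested members had positive values, with a median log2 fold change of 0.74 (limma camera adjusted p = 2.72e-30, and adjusted p = 0.0278 with an estimated correlation). Over all genes 3 members passed (C1qa, C1qb and Fcer1g), and 15 passed adjusted over the list alone. Csf1r, the receptor of a macrophage growth factor, stood at 28.3 ± 2.82 against 17.2 ± 2.96 CPM (edgeR adjusted p = 0.0524), and the class II gene H2-Aa at 80.1 ± 27.3 against 21.7 ± 9.93 CPM (edgeR adjusted p = 0.0574). Apoe, abundant in microglia and macrophages, varied from library to library, at 174 ± 150 against 107 ± 85.1 CPM (edgeR adjusted p = 0.892). The summed markers reached 1496 ± 390 CPM in cKO and 911 ± 19.2 CPM in WT (exact two-sided permutation test, p = 0.00952, and 0.0762 after adjustment over 8 lists). For comparison, the same sum was 715 ± 13.4 CPM in the untreated cultures. NK and CD8 T cell markers rose in camera with a median of 0.72 (limma adjusted p = 0.0171, and adjusted p = 0.383 with an estimated correlation). The sums of T cell, neutrophil, B cell and neural markers had exact two-sided permutation p = 0.948, 0.590, 0.286 and 0.386, and without cKO replicate 2 the B cell sum was lower in cKO with exact p = 0.0159. The sum of NK and CD8 markers was 327 ± 114 against 157 ± 126 CPM (exact two-sided permutation test, p = 0.0333, adjusted 0.133), with Gzma, a cytotoxic granule protease, at 238 ± 104 against 94.4 ± 95.6 CPM. The WT mean rested on WT replicate 3, at 344 CPM, without which it was 94.8 ± 20.4 CPM (exact two-sided permutation test, p = 0.0119), and the p lay above the threshold without any 1 of WT replicates 1, 2 and 4 and cKO replicates 1, 3, 4, 5 and 6 (up to 0.0714). The camera call was lost without WT replicates 1, 2 or 4 or cKO replicate 5 (limma camera adjusted p = 0.056, 0.0745, 0.12 and 0.0688). Without Gzma, the most abundant member, the exact two-sided p was 0.0667.

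Lists that describe T cell states also moved, beside this rise of myeloid markers. The stem-like and memory list fell, with 12 of 13 members negative and a median of −0.42 (limma camera adjusted p = 4.27e-06, and adjusted p = 0.0665 with an estimated correlation). None of its members passed over all genes, and 4 passed adjusted over the list alone. Those were Tcf7, a transcription factor of memory T cells, at 57.6 ± 8.32 against 86.6 ± 13.9 CPM, Bach2 at 3.29 ± 0.831 against 6.77 ± 1.86, the lymph node homing receptor Ccr7 at 24.7 ± 4.83 against 36.7 ± 3.69, and Slamf6 at 29.5 ± 7.26 against 46.4 ± 15.7 CPM. The homeostatic Th17 list fell with a median of −0.32 (limma camera adjusted p = 0.000146, and adjusted p = 0.357 with an estimated correlation), with 10 of 12 members negative and 0 past over all genes in edgeR, and 3 adjusted over the list alone, Tcf7, Slamf6 and Il6st. The Th17 identity list fell with a median of −0.30 (limma camera adjusted p = 0.0109, and adjusted p = 0.383 with an estimated correlation), with 9 of 14 members negative, and lost its call without WT replicate 2 (limma camera adjusted p = 0.195). Adjusted over the list alone 3 members passed, among them the chemokine receptor Ccr6 at 31.3 ± 16.4 against 67.8 ± 12.8 CPM and the cytokine receptor Il23r at 2.13 ± 0.724 against 4.16 ± 0.819 CPM. Il17a itself was at 42.1 ± 18.5 against 58.8 ± 30.9 CPM (edgeR adjusted p = 0.822).

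The Th1 list rose in Cyp11a1 cKO cells, with a median of 0.44 (limma camera adjusted p = 0.000443, and adjusted p = 0.227 with an estimated correlation). Adjusted over the list alone 4 members passed, and 0 passed over all genes in edgeR. They were Il12rb2, a chain of the interleukin 12 receptor, at 37.2 ± 8.84 against 18.7 ± 7.81 CPM, Nkg7 at 718 ± 124 against 480 ± 88.7, the chemokine Ccl5 at 434 ± 73.6 against 259 ± 77.9, and the death ligand Fasl at 25.9 ± 2.64 against 19.9 ± 2.22 CPM. Nkg7, Ccl5 and Fasl are also expressed by NK and CD8 T cells, whose marker sum was 327 ± 114 against 157 ± 126 CPM in the same libraries. Apoptosis genes rose with a median of 0.16 (limma camera adjusted p = 0.00624) and immediate-early genes with a median of 0.14 (adjusted p = 0.00241), with adjusted p = 0.0774 and 0.383 with an estimated correlation. Atf3, Ier3 and Nr4a2 passed adjusted over the immediate-early list alone. Proliferation genes rose with a median of 0.18 (limma camera adjusted p = 0.00241) and glycolysis genes with a median of 0.16 (adjusted p = 0.0158), with adjusted p = 0.613 and 0.569 with an estimated correlation. Without WT replicate 1 the proliferation list turned direction (limma camera adjusted p = 0.886), and without WT replicate 4 it lost its call (adjusted p = 0.0955). Without both, a fit chosen after seeing the data, proliferation genes passed as lower in cKO and glycolysis genes turned as well (limma camera adjusted p = 7.05e-06 and 0.411). The glycolysis list lost its call without WT replicates 1 or 4 or cKO replicate 1 (limma camera adjusted p = 0.545, 0.104 and 0.153), and the immediate-early list without WT replicate 3 (adjusted p = 0.146). The glucocorticoid-induced list had a median of 0.011 (limma camera adjusted p = 0.817) and its member Tsc22d3, a glucocorticoid target, stood at 61.7 ± 14.3 against 61.4 ± 37.6 CPM. The inflammatory Th17, Treg, co-inhibitory, NF-kB, TGF-β, steroid, cholesterol, interferon, migration and T cell identity lists did not pass, with limma camera adjusted p between 0.0591 and 0.951.

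**Figure D1:**
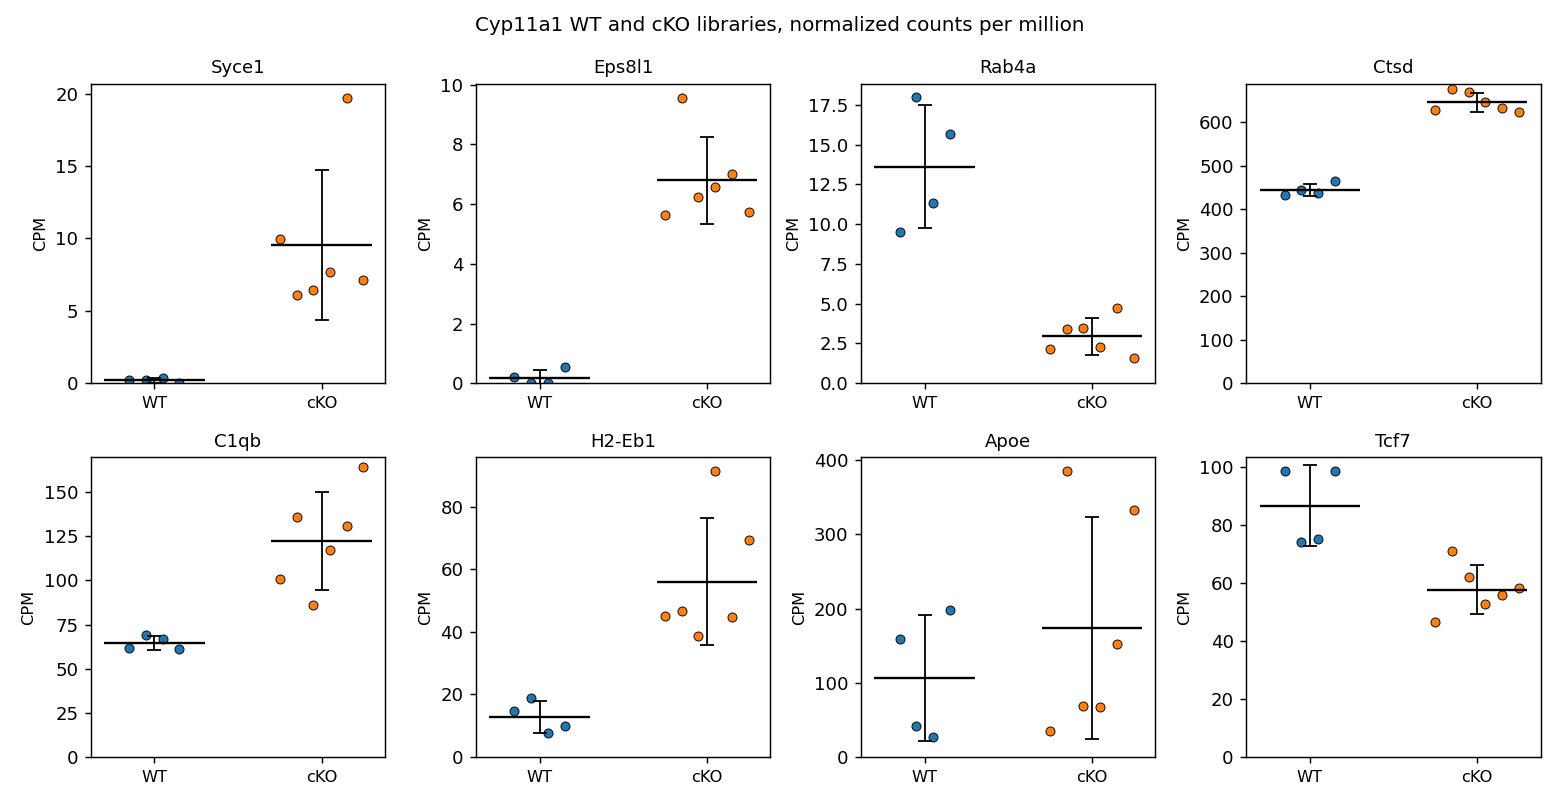
Levels (CPM) of genes compared between Cyp11a1 WT (n = 4) and cKO (n = 6) libraries. Points are libraries, bars the group mean and error bars the SD. Ctsd lay higher in every cKO library than in every WT library, while Apoe overlapped between the groups.

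The GR comparison asked what homeostatic Th17 cells change in the same disease setting when the gene of their glucocorticoid receptor is targeted. Nr3c1 (chromosome 18, 39410545 to 39519421), the targeted gene, stood at 8.43 ± 1.42 CPM in cKO (n = 4) against 14.9 ± 2.38 CPM in WT (n = 5), with counts of 27 to 53 and 43 to 104. Its log2 fold change was −0.83 ± 0.18 and each cKO library lay below each WT library, but it did not pass (edgeR adjusted p = 0.58). Counts per gene do not tell deleted from remaining exons, so this remaining level is not a measure of receptor function. Summed myeloid markers in these libraries ran from 8808 to 27962 CPM, and summed T cell markers from 2349 to 3226 CPM. Levels in the GR comparison, Nr3c1 included, therefore cannot be assigned to the T cells alone. The smallest p-values belonged to Chil3, a chitinase-like protein of macrophages (chromosome 3, 106147554 to 106167564), at 257 ± 94.4 CPM in cKO against 57.7 ± 25.2 CPM in WT, and to Il4i1, an amino acid oxidase gene (chromosome 7, 44816387 to 44840809), at 5.01 ± 0.872 against 11.2 ± 1.96 CPM.

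No gene passed the threshold between GR cKO and WT in edgeR, 0 of 10597, with 870 at an unadjusted p below 0.05 and a smallest adjusted p of 0.455. DESeq2 called 1 gene and limma voom 0. Beside Chil3, the 5 genes of smallest p with higher values in cKO were the chemokine receptor Cxcr3 (chromosome X, 101731535 to 101734269) at 40.8 ± 7.62 against 26.1 ± 1.86 CPM, the inflammatory cytokine Tnf (chromosome 17, 35199381 to 35202007) at 153 ± 23.9 against 102 ± 12.2, Phf21a at 37.7 ± 2.07 against 27.5 ± 2.02, and Unc5cl at 4.33 ± 1.06 against 1.5 ± 0.772 CPM. Those with lower values were Il4i1, Nr3c1, Fcrl1 at 2.27 ± 0.180 against 5.23 ± 0.964 CPM, Xlr3a at 0.558 ± 0.377 against 3.87 ± 1.86, and the histone gene Hist1h2br at 4.93 ± 0.646 against 12.2 ± 4.57 CPM. All of these except Chil3 and Il4i1 had an edgeR adjusted p of 0.58. Cyp11a1 had 0 counts in every library except GR cKO replicate 2, with 13. Glucocorticoid targets did not pass: Tsc22d3 stood at 61.0 ± 13.2 against 67.5 ± 35.5 CPM, Txnip at 48.2 ± 6.94 against 51.1 ± 13.8 CPM and Sgk1 at 111 ± 20.3 against 70.5 ± 36.2 CPM. The glucocorticoid-induced list had a median of 0.14 (limma camera adjusted p = 0.184).

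In the GR comparison 6 of 21 lists passed camera, and 0 of them did with an estimated correlation. Proliferation genes were lower as a list, all 22 negative with a median of −1.23 (limma camera adjusted p = 4.8e-12, and adjusted p = 0.566 with an estimated correlation). No member passed in edgeR, 0 over all genes and 0 adjusted over the list alone. The replication helicase gene Mcm5 stood at 31.0 ± 18.7 against 73.4 ± 44.7 CPM and Tk1 at 19.5 ± 10.9 against 44.5 ± 22.6 CPM. Cholesterol synthesis genes were lower as a list, all 19 negative with a median of −0.53 (limma camera adjusted p = 9.14e-09, and adjusted p = 0.566 with an estimated correlation), and again 0 members passed in edgeR over all genes and 0 adjusted over the list alone. Idi1 stood at 4.98 ± 1.71 against 13.8 ± 8.57 CPM and Dhcr7, which makes cholesterol from its precursor, at 18.1 ± 1.27 against 27.2 ± 7.34 CPM. Glycolysis genes were lower as a list with a median of −0.35 (limma camera adjusted p = 0.00952) and NK and CD8 markers with a median of −0.50 (adjusted p = 0.0186), each with adjusted p = 0.566 with an estimated correlation. The glycolysis call was lost without WT replicate 4 or cKO replicates 1 or 4, and the NK and CD8 call without cKO replicate 4 (limma camera adjusted p = 0.203, 0.0744, 0.0576 and 0.0576). Treg genes fell with 10 of 12 negative and a median of −0.36 (limma camera adjusted p = 0.00259, and adjusted p = 0.167 with an estimated correlation). Il1rl1, the interleukin 33 receptor, was the 1 member past the threshold adjusted over the list alone, at 2.38 ± 0.573 against 5.79 ± 2.11 CPM, and 0 passed over all genes in edgeR. Myeloid markers rose, 19 of 21 positive with a median of 0.28 (limma camera adjusted p = 0.00122, and adjusted p = 0.566 with an estimated correlation), with 0 members past in edgeR over all genes or adjusted over the list alone and C1qc at 507 ± 161 against 378 ± 101 CPM. The Th17 identity, homeostatic Th17, inflammatory Th17, Th1 and other lists did not pass, with limma camera adjusted p between 0.0632 and 0.803, and Il17a stood at 11.1 ± 3.54 against 10.4 ± 5.37 CPM.

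Library composition varied within both GR groups. Summed myeloid markers ran from 15685 to 27645 CPM in cKO and from 8808 to 27962 CPM in WT, against 1026 to 2005 and 885 to 928 CPM in the Cyp11a1 experiment. Summed proliferation genes were 535 ± 344 CPM in cKO and 1161 ± 682 CPM in WT (exact two-sided permutation test, p = 0.151), and summed T cell markers were 2994 ± 164 against 2890 ± 325 CPM (exact two-sided permutation test, p = 0.690). WT replicates 3 and 4 had the highest proliferation sums, 1884 and 1743 CPM, and the lowest myeloid sums, 8808 and 11065 CPM. Neutrophil markers summed to 94.5 ± 9.68 against 62.9 ± 22.7 CPM (exact two-sided permutation test, p = 0.0476, adjusted 0.330 over 8 lists), and lay above the threshold without any 1 of WT replicates 2 to 5 or of the cKO libraries (exact two-sided permutation p from 0.0571 to 0.125). Without WT replicate 3, or without WT replicates 3 and 4, 1 gene passed in edgeR, and 10 lists passed camera without WT replicate 5 and cKO replicate 1, the fits without pairs of libraries being chosen after seeing the data.

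**Figure D2:**
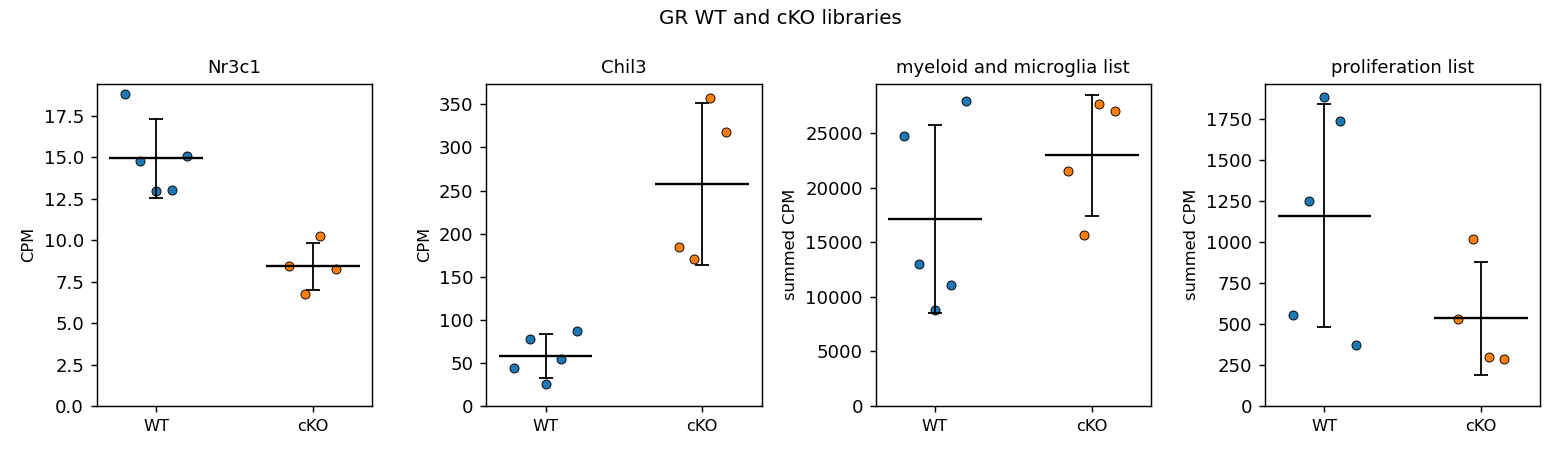
Levels (CPM) of genes compared between GR WT (n = 5) and cKO (n = 4) libraries. Points are libraries, bars the group mean and error bars the SD. Nr3c1 lay lower in each cKO library than in each WT library, and Chil3 higher.

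The Dex comparison asked how inflammatory Th17 cells respond to a glucocorticoid within 2 days. Il2, the T cell growth factor (chromosome 3, 37120523 to 37125959), fell from 90.2 ± 20.9 CPM in controls to 19.2 ± 5.82 CPM with Dex (n = 3 each), and the cytokine Il3 (chromosome 11, 54265303 to 54267277) fell from 70.7 ± 23.7 to 13.5 ± 0.127 CPM. The glucocorticoid target Tsc22d3, which encodes GILZ (chromosome X, 140539528 to 140600659), rose from 47.3 ± 2.50 to 115 ± 5.16 CPM. The costimulatory receptor Icos (chromosome 1, 60977927 to 61000320) rose from 54.5 ± 4.53 to 123 ± 7.11 CPM. Cyp11a1 fell 2.31-fold, from 51.4 ± 4.67 to 22.1 ± 2.97 CPM, with 155 to 198 counts in control libraries and 64 to 93 with Dex. Nr3c1 was at 4.98 ± 1.95 against 3.57 ± 0.851 CPM (edgeR adjusted p = 0.589).

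With Dex, 189 of 10332 genes passed in edgeR, 95 higher and 94 lower, 44 of them by at least 2-fold. Among genes that rose, the log2 fold change was 1.74 ± 0.23 for Ramp3, a subunit of calcitonin-family receptors (chromosome 11, 6658521 to 6677475, edgeR adjusted p = 0.00165), 1.40 ± 0.27 for the kinase gene Sgk1 (chromosome 10, 21882184 to 21999903, adjusted p = 0.0214) and 1.29 ± 0.12 for Tsc22d3 (adjusted p = 9.52e-05). Isg20, Olfr1033, Tgfb3, Enpp2, Icos, Ccr6 and Tspan6 rose by 1.11 to 1.36. Among genes that fell, the log2 fold change was −3.30 ± 0.62 for Il9 (chromosome 13, 56479277 to 56482246, edgeR adjusted p = 0.0255), −2.37 ± 0.36 for Il3 and −2.23 ± 0.38 for Il2. Crabp2, a retinoic acid binding protein gene, fell by 1.52, and the activation-induced nuclear factors Nr4a3 (chromosome 4, 48045153 to 48086447) and Egr2 by 1.41 and 1.31. Cyp11a1, Rgs16, Hivep3 and Cd40 fell by 1.00 to 1.21. The smallest p belonged to Plaur, the urokinase receptor, outside the naming rule by its mean level, at 31.3 ± 2.52 against 3.02 ± 0.966 CPM (edgeR adjusted p = 7.76e-06). Without single control or Dex libraries the count ran from 78 (without control replicate 3 or Dex replicate 1) to 129, and it was 95, 111 and 98 without control replicates 1 and 2 and Dex replicate 2.

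Of 21 lists, 6 passed camera with Dex, 3 of them also with an estimated correlation, and 10 passed without control replicate 2. Th2 genes fell with a median of −0.68 (limma camera adjusted p = 2.52e-15, and adjusted p = 0.00372 with an estimated correlation). Of 7 members 3 passed over all genes and 5 adjusted over the list alone: Il5 went from 30.2 ± 4.47 to 1.95 ± 1.02 CPM, Il13 from 40.3 ± 3.20 to 4.91 ± 2.04 CPM and Il24 from 861 ± 98.8 to 555 ± 58.0 CPM. NF-kB targets and activation cytokines fell with a median of −0.32 (limma camera adjusted p = 2.05e-09, and adjusted p = 0.00791 with an estimated correlation). Of 17 members 5 passed over all genes and 9 adjusted over the list alone, among them Il2, Tnf, which fell from 48.9 ± 11.4 to 26.3 ± 2.01 CPM, and Tnfaip3, an inhibitor of NF-kB signalling, which fell from 70.4 ± 3.71 to 48.9 ± 4.69 CPM. Glucocorticoid-induced genes rose with a median of 0.26 (limma camera adjusted p = 2.59e-08, and adjusted p = 0.0233 with an estimated correlation), 4 of 16 over all genes (Tsc22d3, Sgk1, Txnip and Mt1) and 6 adjusted over the list alone. Th1, cholesterol synthesis and T cell identity genes fell with medians of −0.41, −0.16 and −0.085 (limma camera adjusted p = 0.00756, 0.0094 and 0.014), with adjusted p = 0.151, 0.300 and 0.155 with an estimated correlation. Without Dex replicate 1 the Th1 list, and without control replicate 3 the other two, lost their calls (limma camera adjusted p = 0.0627, 0.0823 and 0.0721). Among Th1 and cholesterol members 4 and 2 fell adjusted over the list alone, where over all genes none did, and 4 T cell identity members fell and 3 rose, against 3 and 1 over all genes. Lat and Cd5, which belong to T cell receptor signalling, were among the T cell members that fell over all genes. The Th17 identity list did not pass (limma camera adjusted p = 0.805), and only Ccr6 among its members passed over all genes. The other lists had limma camera adjusted p between 0.0636 and 0.892.

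The TGF-β1 comparison asked how the same cells respond to TGF-β1, which favours homeostatic over inflammatory Th17 cells. Il9 rose from 35.3 ± 15.6 to 301 ± 112 CPM (n = 3 each), the Th17 cytokine Il17f (chromosome 1, 20777146 to 20790617) from 11.9 ± 7.08 to 56.1 ± 20.5 CPM and the chemokine receptor Ccr6 (chromosome 17, 8236043 to 8257141) from 9.05 ± 1.82 to 56.6 ± 9.24 CPM. The Th2 regulator Gata3 (chromosome 2, 9857078 to 9890034) fell from 112 ± 6.19 to 31.2 ± 3.23 CPM and Il4 (chromosome 11, 53602982 to 53618669) from 47.4 ± 4.84 to 11.6 ± 3.43 CPM. Cyp11a1 stood at 61.6 ± 4.00 against 51.4 ± 4.67 CPM (edgeR adjusted p = 0.273), and Nr3c1 at 3.36 ± 0.777 against 3.57 ± 0.851 CPM.

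With TGF-β1, 340 of 10332 genes passed in edgeR, 199 higher and 141 lower, 119 of them by at least 2-fold. The largest named log2 fold changes were 4.01 ± 0.29 for Aqp3, a channel for water and glycerol (chromosome 4, 41092722 to 41098183, edgeR adjusted p = 5.5e-06), 3.45 ± 0.24 for the protease gene Ctsw (chromosome 19, 5465043 to 5468507) and 3.10 ± 0.38 for Il9. Ccr6 rose by 2.65 ± 0.22 and Timp1, an inhibitor of matrix proteases (chromosome X, 20870166 to 20874735), by 2.47 ± 0.18. Il17f, AA467197, Ctla2b, Acsbg1 and Ctla2a rose by 1.65 to 2.25. Among genes that fell, the log2 fold change was −2.43 ± 0.37 for Il3, −2.02 ± 0.26 for Il4 and −1.85 ± 0.24 for Gata3 (edgeR adjusted p = 0.000735). The inhibitory receptor Tigit (chromosome 16, 43648867 to 43664146) fell by 1.54 and granzyme B, Gzmb (chromosome 14, 56258838 to 56262260), by 1.59, while Trat1, Lilr4b, Serpinb6b, Serpine2 and Lilrb4a fell by 1.52 to 1.92. Without control replicates 1 or 3 or TGF-β1 replicate 1 the count was 226, 219 and 219.

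Of 21 lists, 8 passed camera with TGF-β1, and 6 also with an estimated correlation. TGF-β and Smad targets rose with a median of 0.62 (limma camera adjusted p = 1.37e-06, and adjusted p = 0.00317 with an estimated correlation), 7 of 15 over all genes and 8 adjusted over the list alone, such as the Smad regulators Skil, from 11.2 ± 1.47 to 22.6 ± 0.618 CPM, and Ldlrad4, from 1.25 ± 0.236 to 6.77 ± 1.94 CPM. Homeostatic Th17 genes rose with a median of 0.66 (limma camera adjusted p = 3.09e-07, and adjusted p = 0.00317 with an estimated correlation), 4 of 11 over all genes: Il9, Izumo1r, the interleukin 1 antagonist Il1rn and the transcription factor Maf, from 1.37 ± 0.327 to 4.21 ± 0.424 CPM. Th17 identity genes rose with a median of 0.42 (limma camera adjusted p = 1.27e-08, and adjusted p = 0.0302 with an estimated correlation). Over all genes 5 of its 11 members rose, among them Ccr6, Il17f and Rora, from 19.5 ± 0.331 to 45.4 ± 3.92 CPM, and 1 fell, Batf, from 255 ± 11.6 to 150 ± 18.6 CPM. Th2 genes fell with a median of −1.85 (limma camera adjusted p = 6.33e-14, and adjusted p = 0.00286 with an estimated correlation), 4 of 7 over all genes, Il4, Gata3, Il5 and Il13. Migration receptors rose with a median of 0.29 (limma camera adjusted p = 6.84e-08, and adjusted p = 0.00286 with an estimated correlation), 5 up, among them Ccr7 and Ccr6, and 1 down. NF-kB targets rose with a median of 0.20 (limma camera adjusted p = 4.22e-06, and adjusted p = 0.0170 with an estimated correlation), led by the lymphotoxin gene Lta, from 225 ± 8.28 to 648 ± 24.2 CPM. Th1 genes fell with a median of −0.62 and immediate-early genes rose with a median of 0.20 (limma camera adjusted p = 0.00852 and 0.00431), with adjusted p = 0.121 and 0.229 with an estimated correlation, and the Th1 call was lost without TGF-β1 replicate 1 (adjusted p = 0.0729). Adjusted over the list alone, 7 Th17 identity, 6 homeostatic Th17, 8 migration and 5 NF-kB members rose and 1, 1, 1 and 2 fell, while 4 Th2 members fell and 1 rose. The other lists had limma camera adjusted p between 0.0784 and 0.992.

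**Figure D3:**
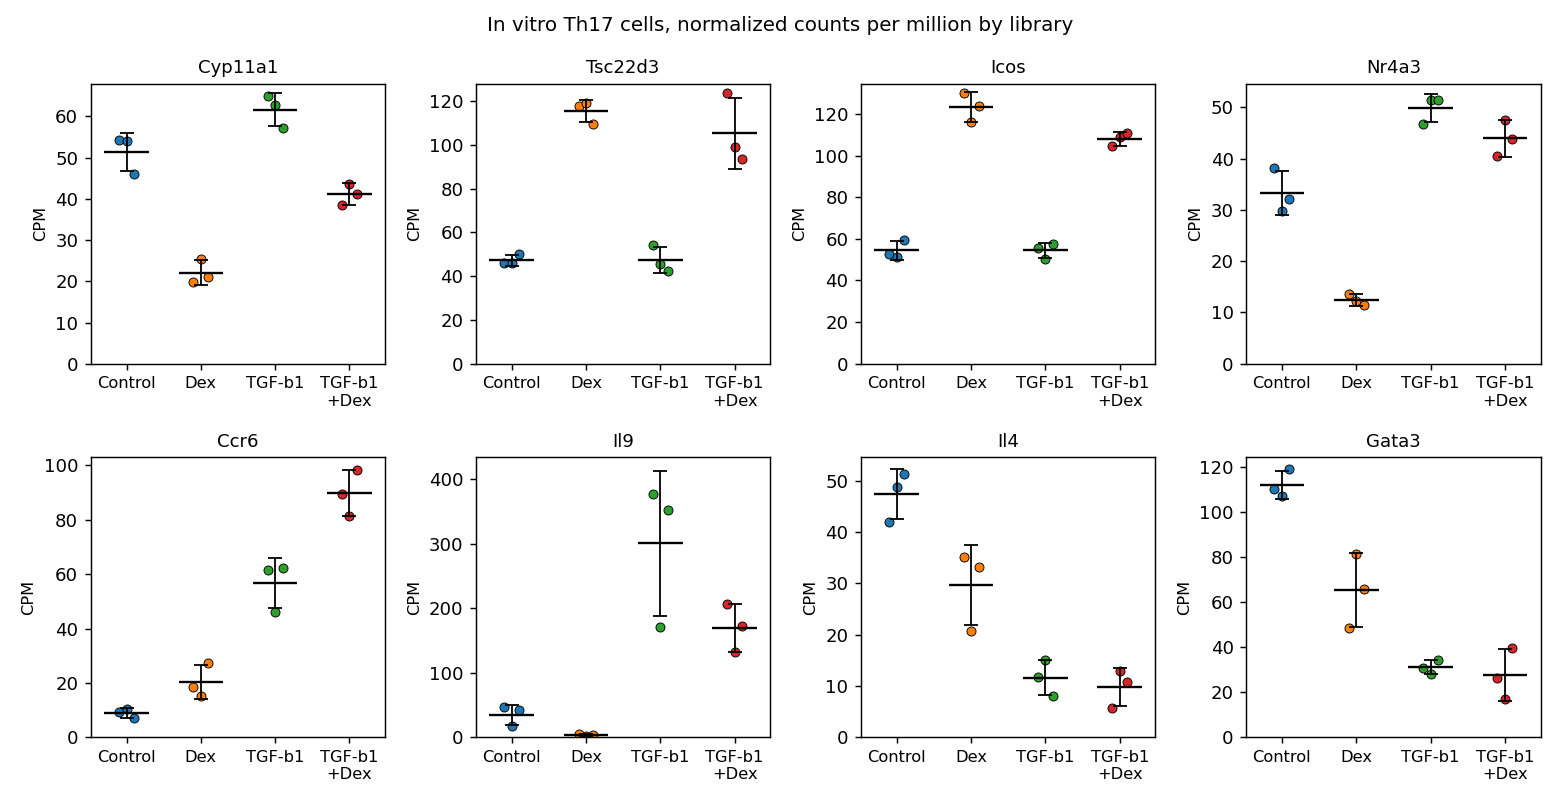
Levels (CPM) of genes in inflammatory Th17 cultures without addition, with Dex, with TGF-β1 and with both (n = 3 each). Points are libraries, bars the group mean and error bars the SD. Cyp11a1 was lowest with Dex alone, at 22.1 CPM on average, and Tsc22d3 was raised in both groups with Dex.

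The combination of TGF-β1 and Dex was compared with untreated cells, to show their joint effect. Ccr6 rose from 9.05 ± 1.82 to 89.8 ± 8.42 CPM (n = 3 each), and Gzmb fell from 655 ± 59.8 to 100 ± 28.4 CPM. Il3 fell from 70.7 ± 23.7 to 2.81 ± 3.09 CPM, and Sgk1 rose from 6.50 ± 1.70 to 29.8 ± 4.56 CPM. In edgeR, 646 genes passed, 322 higher and 324 lower, 204 by at least 2-fold, and 429 and 425 passed without control replicate 1 and combination replicate 1. Aqp3 rose by 4.05 ± 0.29, Ccr6 by 3.32 ± 0.22 and Ctsw by 3.08 ± 0.24, and Ctla2b, Il9, Il17f, Sgk1, Ctla2a, Timp1 and Acsbg1 by 2.07 to 2.45. The log2 fold change was −4.65 ± 0.46 for Il3 and −2.71 ± 0.27 for Gzmb, and Il4, Trat1, Gata3, Lilr4b, Lilrb4a, Tigit, Nudt1 and Serpine2 fell by 1.62 to 2.26. Cyp11a1 stood at 41.1 ± 2.65 against 51.4 ± 4.67 CPM (edgeR adjusted p = 0.128).

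Of 21 lists, 9 passed in the combination, and 7 also with an estimated correlation. Inflammatory Th17 genes fell with a median of −0.71 (limma camera adjusted p = 0.000718, and adjusted p = 0.0218 with an estimated correlation), 5 down over all genes (Il3, Gzmb, Stat4, Lag3 and Lgals3) and 2 up (Icos and Il18r1). Th1 and Th2 genes fell with medians of −1.07 and −1.97 (limma camera adjusted p = 3.24e-06 and 3.37e-21, and adjusted p = 0.0155 and 0.000168 with an estimated correlation). Il5 and Il13 averaged 0.437 and 0.581 CPM, below the level that a count of 0 allows. Homeostatic Th17, glucocorticoid-induced and TGF-β target genes rose with medians of 0.60, 0.44 and 0.28 (limma camera adjusted p = 0.00272, 5.61e-06 and 0.00272, each with adjusted p = 0.0264 with an estimated correlation). Migration receptors rose with a median of 0.076 (limma camera adjusted p = 6.63e-05, and adjusted p = 0.0155 with an estimated correlation). Th17 identity genes rose with a median of 0.45 (limma camera adjusted p = 2.24e-05, and adjusted p = 0.0932 with an estimated correlation) and interferon response genes fell with a median of −0.59 (adjusted p = 0.01, and adjusted p = 0.276 with an estimated correlation), a call lost without combination replicates 1 or 3 (adjusted p = 0.132 and 0.0814). Inflammatory Th17, Th1 and Th2 members that fell numbered 8, 8 and 5 adjusted over the list alone, against 5, 4 and 5 over all genes. Of Th17 identity, homeostatic Th17, glucocorticoid-induced and TGF-β target genes 6, 5, 7 and 4 rose adjusted over the list alone, against 5, 4, 6 and 4 over all genes.

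Adding Dex to TGF-β1 raised 32 genes and lowered 23 in edgeR, 12 of the 55 by at least 2-fold. Sgk1 rose from 12.9 ± 4.90 to 29.8 ± 4.56 CPM, Tsc22d3 from 47.4 ± 6.00 to 105 ± 16.2 CPM and Icos from 54.4 ± 3.72 to 108 ± 3.25 CPM, with log2 fold changes of 1.23, 1.15 and 0.99. The adhesion receptor Cd226, Pik3cg, Ecm1, Gpr18, Gng2, Prnp and the ferritin gene Fth1 rose by 0.67 to 0.88. Cyp11a1 fell from 61.6 ± 4.00 to 41.1 ± 2.65 CPM (log2 fold change −0.58 ± 0.11, edgeR adjusted p = 0.0396), and Crabp2, Gsn, Tnfsf8, Avpi1, Stat5a, Nr4a1, Cinp, Tnfaip3 and H2-DMa fell by 0.56 to 0.84. Of 12 lists that passed, 5 did so with an estimated correlation: inflammatory Th17, Th1, Th2 and NF-kB genes fell with medians of −0.42, −0.62, −0.32 and −0.20 (limma camera adjusted p = 0.00154, 0.000259, 3.99e-06 and 2.48e-12), and glucocorticoid-induced genes rose with a median of 0.12 (adjusted p = 9.24e-06). Adjusted over the list alone 6 inflammatory Th17, 4 Th2 and 8 NF-kB members fell and 5 glucocorticoid-induced members rose, against 0, 0, 3 and 3 over all genes in edgeR. The other 7, homeostatic Th17, Treg, co-inhibitory, interferon, immediate-early and T cell identity genes, which fell, and proliferation genes, which rose, had adjusted p between 0.0523 and 0.275 with an estimated correlation (limma camera). Of these, the Treg call was lost without TGF-β1 replicates 1 or 3 or combination replicate 2, the interferon call without TGF-β1 replicate 2 or combination replicates 1 or 3, the homeostatic Th17 call without TGF-β1 replicate 3 or combination replicates 1 or 3, the immediate-early call without TGF-β1 replicate 3 or combination replicate 2, and the proliferation call without combination replicate 2 (limma camera adjusted p from 0.0739 to 0.319). The count was 22 when only the groups compared were fitted, 88 in DESeq2, and 24 to 35 without single libraries of either group, the lowest without TGF-β1 replicates 1 or 2.

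Adding TGF-β1 to Dex raised 151 genes and lowered 120 in edgeR, 97 of the 271 by at least 2-fold. Il9 rose from 3.60 ± 1.73 to 170 ± 37.2 CPM and the nuclear receptor Nr4a3 from 12.4 ± 1.10 to 43.9 ± 3.55 CPM. Cyp11a1 rose from 22.1 ± 2.97 to 41.1 ± 2.65 CPM (log2 fold change 0.89 ± 0.12, edgeR adjusted p = 0.00144). Ctsw and Aqp3 rose by 3.81 and 3.29, and Timp1, Ccr6, AA467197, Anxa3, Cd40 and Acsbg1 by 1.42 to 2.34. Il3 fell by 2.28, and Serpinb6b, Lilr4b, Lilrb4a, Ramp3, Gzmb, Il4, Tigit, the chemokine Ccl5 and Gbp4 by 1.45 to 1.78. Of 12 lists that passed, 8 did so with an estimated correlation: Th17 identity, homeostatic Th17, NF-kB, TGF-β target, steroid and migration lists rose, with medians of 0.53, 0.17, 0.20, 0.39, 0.21 and 0.07, and inflammatory Th17 and Th2 genes fell with medians of −0.44 and −1.20 (limma camera adjusted p at most 0.00058). Adjusted over the list alone 6 Th17 identity, 5 NF-kB and 5 TGF-β target members rose and 7 inflammatory Th17 and 5 Th2 members fell, against 4, 4, 2, 3 and 3 over all genes. Th1 and interferon genes, which fell, and cholesterol and immediate-early genes, which rose, had adjusted p between 0.0633 and 0.336 with an estimated correlation (limma camera), and the cholesterol and immediate-early calls were lost without combination replicate 3 (adjusted p = 0.163 and 0.0638). The count was 152 and 158 without Dex replicates 2 and 3, and 155 and 166 without combination replicates 1 and 3.

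Whether Dex acted differently in the presence of TGF-β1 was tested by the interaction. No gene passed in edgeR, 0 of 10332, with 552 at an unadjusted p below 0.05 and 2 genes called by DESeq2. The smallest adjusted p was that of Nr4a3 (log2 interaction 1.23 ± 0.17, edgeR adjusted p = 0.0978), which averaged 33.3 ± 4.34 CPM in controls, 12.4 ± 1.10 CPM with Dex, 49.9 ± 2.66 CPM with TGF-β1 and 43.9 ± 3.55 CPM with both. For Cyp11a1 the interaction was 0.63 ± 0.16 (edgeR adjusted p = 0.74). After adjustment over all 10332 genes, its falls with Dex in the absence and presence of TGF-β1 were thus not shown to differ. The positive estimate is that of a smaller fall in the presence of TGF-β1. Cyp11a1 was named in advance, and a p for this gene alone, without that adjustment, is not given here. Rpl35, Ndufa4, Hist1h2bl and Agrp were the other genes of smallest p with positive interaction, and C1qtnf12, Asrgl1, Alg11, Ptpn3 and Tmem104 those with negative interaction, with edgeR adjusted p between 0.148 and 0.74. None of the 21 lists passed, the smallest limma camera adjusted p being 0.0672 for interferon genes. Of the 189 genes called with Dex alone, 179 moved the same way when Dex was added to TGF-β1, 44 passed there too and 172 had a smaller effect. In reverse, of the 55 genes called for Dex added to TGF-β1, 51 moved the same way with Dex alone and 25 had a smaller effect there. Of the 340 called with TGF-β1 alone, 322 moved the same way when it was added to Dex, 170 passed there too and 266 had a smaller effect, and of the 271 called for TGF-β1 added to Dex, 261 moved the same way with TGF-β1 alone and 175 had a smaller effect there. These genes were picked for passing in 1 of the comparisons, which alone favours smaller effects in the other.

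Dex and TGF-β1 shared 19 genes that rose with each and 26 that fell with each, where 1.83 and 1.28 would be shared by chance, and 10 moved in opposite directions. Il3, Il5 and Il13 were among those that fell with each, while Il9 fell with Dex and rose with TGF-β1. Both effects were measured against the same 3 control libraries, which raises such overlaps and is not part of these chance values. In 50 simulated experiments with unchanged groups and shared controls, at most 1 gene was called the same way in both, against 45 here. Those experiments called 0.08 genes on average in each comparison, so they do not give the overlap of groups with many changes. Across genes, which are not independent replicates, the correlation of the effects was 0.452, against 0.498 ± 0.0359 in simulations, and their covariance 0.128, against 0.0595 ± 0.00681. Shared controls alone give such a correlation in unchanged groups, so it does not tell a shared response from the shared controls. The covariance lay above all simulated values, which ran from 0.0481 to 0.0794. The genes that moved in vitro were then followed in the knockout cells. Of 8 tests only 1 passed: the 128 tested genes that fell with TGF-β1 were lower in GR cKO cells, with a median of −0.17 and 22.7% of them positive (limma camera adjusted p = 5.59e-06, and adjusted p = 0.750 with an estimated correlation). The genes that rose or fell with Dex showed no shift in GR or Cyp11a1 cKO cells that passed, with limma camera adjusted p between 0.137 and 0.974. Of the genes called in Cyp11a1 cKO cells, 8 higher and 3 lower ones were also tested in vitro. With Dex 0 of them were called the same way in edgeR, where 0.0744 higher and 0.025 lower would be by chance, so this decides nothing on shared genes. With TGF-β1 1 rose, where 0.146 would by chance, and 0 fell, where 0.0414 would.

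Median, mean and camera direction differed in sign for some lists, none of which passed camera in that comparison. These were the glucocorticoid-induced, TGF-β and interferon lists in Cyp11a1 cKO, the inflammatory Th17, Th1 and migration lists in GR cKO, and the Th17 identity, stem-like, steroid, interferon and myeloid lists with Dex. With TGF-β1 they were the stem-like and T cell identity lists, and in the combination against controls the co-inhibitory, stem-like and cholesterol lists. They were the steroid, apoptosis and migration lists for Dex added to TGF-β1, the Treg, stem-like, T cell identity and myeloid lists for TGF-β1 added to Dex, and the Th1, NF-kB and T cell identity lists in the interaction.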

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

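In this part, the test of the ratio of Apoe to C1qb counts was chosen after the result was seen, as were the fits with a covariate and the simulation on them; the test of the second myeloid list and the splits of the libraries were chosen before. Of 80 groups of 4 to 10 libraries tested for a library far from the others, 6 held one, where chance gives about 5%. In total counts, Cyp11a1 WT replicate 4 stood at 4358651 against 4930752 to 4983932 in the other WT libraries. The B cell and plasma cell sum was 33.7 CPM in Cyp11a1 cKO replicate 2 against 11.9 to 16.5 CPM in the others, and the NK and CD8 T cell sum 344 CPM in Cyp11a1 WT replicate 3 against 82.0 to 118 CPM. Tmem254c stood at 23.5 CPM in Cyp11a1 cKO replicate 4 against 17.0 to 19.4 CPM. GR WT replicate 2 had the highest Tnf among WT libraries, 123 CPM against 92.5 to 99.4, and the highest Unc5cl, 2.84 CPM against 1.02 to 1.48. The B cell and the NK and CD8 sums were also compared without these libraries, and the other 4 values were not followed further.

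The rise of myeloid markers in Cyp11a1 cKO libraries was weighed against technical sources. The share of repeat-like predicted genes was similar, 23.3 ± 5.92% in cKO against 25.3 ± 9.0% in WT, which argues against it as the whole cause. The myeloid list still passed with that share as a covariate (limma camera at the preset correlation, adjusted p = 3.13e-29). A share so similar in both groups could hardly have removed the difference, so this fit adds little. RNA of myeloid cells in the sorted fraction is a candidate explanation: a second list of 24 myeloid genes, none of them in the first, had a median log2 fold change of 0.58 and 20 of 22 tested members positive (limma camera p = 4.58e-12, and p = 0.00419 with an estimated correlation), while cultured Th17 cells expressed 6 of the 24 and 8 of the 21 genes of the first list. The ratio of Apoe to C1qb counts ranged 9.40-fold over the libraries and as widely inside WT, from 0.404 to 3.26, as inside cKO, from 0.347 to 2.84. The lowest counts were 155 for Apoe and 230 for C1qb, so counting error alone does not give this range. It argues against 1 source of fixed composition for Apoe and C1qb. Whether the other markers shared 1 source is not answered by this ratio. Of the abundant genes of the first list, Cst3 stood at 358 ± 51.7 against 336 ± 80.8 CPM, Apoe at 174 ± 150 against 107 ± 85.1 and C1qb at 123 ± 27.7 against 64.6 ± 3.87 CPM in cKO and WT. Sorting for the 2D2 receptor is meant to remove such cells. In the GR experiment, also of sorted 2D2 cells, summed myeloid markers nevertheless ran from 8808 to 27962 CPM. The sort by itself therefore does not argue against myeloid RNA in the sorted fraction. Myeloid genes made by the T cells themselves, or a biological change in the cells that surround them, stay open as untested.

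In the Cyp11a1 comparison, 1 of 100 splits of the 10 libraries, the real one, gave as many as 18 genes, and the highest other gave 7. Chance is therefore an unlikely source of the gene count. It is not excluded, since 100 of 210 possible splits were run and the labels do not state whether the libraries are independent. For the 10 gene lists chance remains a plain possibility: 14 of 100 splits gave as many, and the highest other gave 14. In the GR comparison, 15 of 100 splits gave as many genes at an unadjusted p below 0.05 as the real one, 870 genes against a highest other of 3646. For its 6 lists 39 of 100 splits gave as many, and the highest other gave 13, so chance is not excluded for either.

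The absence of called genes in the GR comparison, 0 in edgeR, was weighed against the spread between its libraries. A count of 0 is reached by any split, here 100 of 100, so the splits decide nothing on chance. The highest other split gave 2057 genes, which points to a structure of the samples that follows genotype only in part. That split set WT replicates 2, 3 and 4 and cKO replicate 2 against WT replicates 1 and 5 and cKO replicates 1, 3 and 4. The libraries of the first set had the lowest summed myeloid markers, 8808 to 15685 CPM, and the highest summed proliferation genes, 1022 to 1884 CPM. With the myeloid marker sum or the repeat share as a covariate 0 genes passed in edgeR, with 544 and 749 at an unadjusted p below 0.05, but of 200 genes changed 1.5-fold by thinning the real counts these fits recovered 32 and 0, and of 200 changed 2-fold 142 and 103, against 0 and 122 without a covariate. The changed genes had a mean log2 CPM above 3. At such levels, the 0 calls argue against many 2-fold changes in the RNA of whole libraries hidden by varying myeloid RNA or repeat share. The thinning did not cover a change in the T cells alone of genes that other cells in a library also express. On such changes the 0 calls decide nothing. The repeat share as a covariate did not raise recovery, with 0 and 103 against 0 and 122. Changes of 1.5-fold were mostly missed, so varying myeloid RNA or repeat share cannot be told apart from a small effect of the knockout. Remaining receptor or other differences between recipients stay open as untested.

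For the in vitro comparisons the 10 splits of 3 against 3 libraries are too few for a share below 0.05. In genes, the real value and the highest other were 189 and 1 for Dex, 340 and 1 for TGF-β1, 646 and 0 for the combination, 55 and 0 for Dex added to TGF-β1, and 271 and 0 for TGF-β1 added to Dex, and 1 of 10 splits, the real one, reached the real value each time. In lists, they were 6 and 4, 8 and 3, 9 and 6, 12 and 6, and 12 and 9. For the interaction, where 0 genes passed in edgeR and 552 stood at an unadjusted p below 0.05, 100 of 100 random assignments reached that count of 0, as any would, and the highest other gave 7, so this decides nothing on chance.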

How the results depend on the processing

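The tests chosen after seeing the data here are those without the repeat-like genes, those with a covariate, those without pairs of libraries and the marker sums without single libraries. Of the values recomputed for genes, 5461 kept direction and side of the threshold, 357 lost the threshold, 60 gained it and 19 reversed. Of list results 686 kept theirs, 94 were weaker and 4 reversed, and of counts 410 stayed within 1.5 times and 128 moved, 77 of these without a single library. The cause of a change was not tested except where libraries or genes are fewer. Low counts limit the comparison of Cyp11a1 in the nervous system, 0 to 13 against 64 to 217 in the cultures, whose libraries held at most 4291149 counts, and that of Nr3c1 in vitro, 9 to 23.

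In Cyp11a1 cKO, 33 genes passed with no filter, 60 in DESeq2, 6 in limma voom, 3 with the myeloid sum as a covariate and 6 without WT 1 and 4. Without single libraries 9 to 22 passed. Lists numbered 1 with an estimated correlation and 3 in fry. Nr3c1, at −0.01, turned to 0.018 with the repeat share as a covariate and 0.25 without WT 1 and 4, and ran from −0.13 to 0.085 without single libraries. Without WT 1 and 4, Pcna, Birc5, Tk1 and Top2a turned to −0.10, −0.045, −0.076 and −0.056, and the proliferation and glycolysis lists turned (limma camera adjusted p = 7.05e-06 and 0.411). Without single libraries the proliferation list ran from 1.43e-07 to 0.886, turning without WT 1 (limma camera adjusted p).

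In GR cKO, 1 gene passed in DESeq2 and 1 without WT 3 and 4, and 0 to 1 without single libraries. Lists numbered 10 without WT 5 and cKO 1, 0 with an estimated correlation and 1 in fry. The myeloid list turned with its own sum as a covariate (limma camera adjusted p = 0.646), which that fit removes, and Cd8b1 ran from −0.35 to 0.024 without single libraries, turning without cKO 3.

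In vitro, without single libraries, 78 to 129 genes passed for Dex, 219 to 259 for TGF-β1, 425 to 502 for the combination, 24 to 35 for Dex added to TGF-β1, 152 to 203 for TGF-β1 added to Dex and 0 to 1 for the interaction. Lists ran from 4 to 10 for Dex and 0 to 2 for the interaction. With an estimated correlation 3 lists passed for Dex and 5 for Dex added to TGF-β1, and 13 in fry for TGF-β1. Dex added to TGF-β1 gave 22 genes with only the groups compared and 88 in DESeq2. The interaction gave 4 genes with no filter and 2 in DESeq2. Nr3c1 turned to 0.026 with the repeat share as a covariate for TGF-β1. Without single libraries it ran from −0.24 to 0.11 for TGF-β1, −0.10 to 0.34 in the combination, −0.022 to 0.39 for Dex added to TGF-β1 and −0.51 to 0.076 in the interaction. Shared genes at an adjusted p of 0.01 were 4 higher, 9 lower and 2 opposite (edgeR), and the genes that fell with TGF-β1 lost their call in GR cKO (limma camera adjusted p = 0.750 with an estimated correlation).

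Whether replicate numbers paired the libraries was not settled. Correlations of same-numbered libraries exceeded 0.1 in 0 of 4, 1 of 4 and 4 of 18 pairs of the Cyp11a1, GR and in vitro experiments. In vitro they ran from −0.056 to 0.21, and libraries of different numbers were not compared as a baseline. With a replicate block 1 gene passed in Cyp11a1 cKO, where Nr3c1 turned to 0.046, 11 lists passed in GR cKO, and 2 genes and 1 list in the interaction.

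Without the most abundant member, marker sums turned (log2 differences) for T cell identity (−0.017) and neutrophils (0.29) in Cyp11a1 cKO, B cells in GR cKO (0.10), myeloid markers with Dex (0.054) and TGF-β1 (−0.071), neural markers with TGF-β1 (−0.10), B cells with TGF-β1 added to Dex (0.15) and NK and CD8 markers in the combination (0.13). The NK and CD8 sum in Cyp11a1 cKO weakened to 0.61. Without single libraries the sums ran, in Cyp11a1 cKO, from −0.016 to 0.021 for T cell identity, −0.54 to −0.24 for B cells, 1.05 to 1.74 for NK and CD8 markers and −0.0029 to 0.30 for immediate-early genes, and in GR cKO from −0.015 to 0.095 for T cell identity, 0.42 to 0.81 for neutrophils and −0.20 to 0.076 for B cells. Neutrophil sums without that member gave no value in some in vitro comparisons, being 0.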

Other observations

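The tests of gene positions in this part were chosen after the result was seen, as were the genes named. In vitro, Nt5e, the ectoenzyme CD73, rose from 1.35 ± 0.350 to 13.2 ± 3.63 CPM with TGF-β1 (n = 3 each, edgeR adjusted p = 3.28e-05), and Pdpn from 6.36 ± 1.5 to 18.9 ± 1.44 CPM (edgeR adjusted p = 0.00147), while Tigit fell. Treg-associated genes did not move as a list but 4 members rose with TGF-β1, among them Gpr83, from 7.31 ± 0.653 to 15.1 ± 2.86 CPM, and Ikzf4, from 43.9 ± 13.7 to 81.7 ± 2.99 CPM, and Ccr8 fell. Tspo, which encodes a protein of the outer mitochondrial membrane that binds cholesterol, rose from 464 ± 21.6 to 659 ± 38.1 CPM (edgeR adjusted p = 0.000162). With Dex the apoptosis gene Bcl2l1 fell from 127 ± 8.83 to 93.0 ± 6.02 CPM.

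The genes called between Cyp11a1 cKO and WT cells lay close together on the chromosomes more often than random tested genes. Among the 18 genes, 5 pairs lay within 5 Mb of each other, where random draws of tested genes gave 0.934 on average (permutation test with 10000 draws, one-sided p = 0.0054), and 4 pairs outside the myeloid list (p = 0.0088). The pairs were formed by Syce1, Ifitm2 and Ctsd on chromosome 7, Gm42047 and Rab4a on chromosome 8, and C1qa and C1qb on chromosome 4, the last being neighbours in a complement gene cluster. A candidate explanation is that the cKO donors carried chromosome segments of another strain that the WT donors lacked, which is a hypothesis found and tested on the same data. A segment around the targeted locus is excluded for these genes, since 0 of the 18 lay within 20 Mb of Cyp11a1.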
